A study of Drosophila melanogaster with 12 samples.

How the data were processed

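RNA-seq libraries were made from S2 cells, a Drosophila melanogaster line of embryonic origin with features of hemocytes, the insect's macrophage-like blood cells. Per the labels' protocols, cells were treated with 1 µg of double-stranded RNA (dsRNA) against GFP, the control, or against porthos (CG9253). They were passaged 48 h later and harvested 3 days after that. Cells were exposed to 100 µg/ml cycloheximide, which holds ribosomes on mRNA, for 3 min before lysis. From each lysate 20% was kept as input, and the rest was separated on a 10 to 50% sucrose gradient to collect polysomes, the mRNAs that carry several ribosomes. RNA of inputs was extracted with TRIzol and RNA of polysome fractions with phenol and chloroform, so the extraction differed between input and polysome libraries and not between dsRNA treatments. All libraries were poly(A)-selected and made with a directional kit. The 12 libraries fall into 4 groups of 3: input and polysome, each with GFP and with porthos dsRNA. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

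The deposited files hold whole-number read counts per FlyBase gene identifier, 1 file per library. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts 1.4.6 were used, with genome build dm6. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of genes that overlap a gene on the opposite strand, and of members of multigene families, are therefore uncertain. The files list 17023 identifiers, of which 16647 matched a symbol in an Ensembl annotation of the same assembly. The other 376 held 5.29% of all counts, and 206 of them were among the genes tested. Coordinates are from that annotation, in dm6, counted from 1. Gene lengths are the summed exon length of a gene in it, known for 8818 of the genes tested (97.7%).

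Depth ranged from 7559406 counts (polysome, GFP dsRNA, replicate 3) to 11918941 counts (input, porthos dsRNA, replicate 3). A floor of 3 counts corresponds to between 0.252 and 0.397 CPM, the count scaled to a common library total, and covers counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates was alike within counting noise. The lowest chi-square per degree of freedom between replicates was 2.30, and correlations of log CPM within groups ran from 0.978 to 0.994.

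From the deposited counts, CPM values were computed with TMM scaling (edgeR 4.0.16, R 4.3.3). Genes were kept by filterByExpr, which left 9024. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with a term per group. The design was fixed before the data were examined. It had 5 contrasts: porthos against GFP dsRNA in input, the same in polysome fractions, the difference between these changes, and polysome against input within each dsRNA treatment. The difference of changes is called translational efficiency here. It is an interaction term and is relative to the average mRNA, so that a change shared by all mRNAs cannot be seen. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05. Standard errors are the log2 change divided by the square root of the F statistic, and the common biological coefficient of variation was 0.0792. Errors of CPM are SD over 3 libraries.

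Gene lists, 28 in all, were fixed beforehand: 5 lists of nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) complexes I to V and their union, mitochondrially encoded mRNAs, cytoplasmic and mitochondrial ribosomal proteins, TCA cycle, glycolysis, mitochondrial import and chaperones, ribosome biogenesis (without porthos), cytosolic translation factors, proteasome, ATF4 targets, p53, Xrp1 and cell death, heat shock proteins, immune effectors, RNA interference machinery, cell cycle and DNA replication, replication-dependent histones, noncoding RNAs, plasmatocyte markers, crystal cell and lamellocyte markers, germline markers, markers of neuron, muscle and fat body, and protein secretion. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. In 10 of the 104 list tests over 4 contrasts, the sign of the median or the mean differed from the direction of the test, and 0 of these 10 passed the threshold.

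Genes named in the text were chosen by a rule fixed beforehand. For each porthos contrast it took porthos, the 8 genes with the largest change in each direction among those called with at least 10 CPM in a group, and up to 4 members per list with the smallest p. For input and polysome, the 3 porthos libraries had also to lie apart from the 3 GFP libraries. For polysome against input it took 5 genes per direction, and atos and CG9331, which are among the genes the study is about, were added. LKRSDH, another such gene, was not matched to an identifier and is not reported here. Other members that passed the test are named where a list is described, and were chosen after their values were seen.

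The tests were tried on simulated counts drawn for the 9024 genes from each gene's mean and dispersion over all libraries and the real library sizes. Changes were put only into genes with a mean of at least 10 CPM. The counts held neither the length trends nor the outlying library of the real data. The shares below do not cover genes under 10 CPM or those features. For input, edgeR recovered 92% of 1.5-fold and 100% of 2-fold changes, and 4.48% of its calls were false. For polysome it recovered 92% and 100%, with the same share of false calls. For translational efficiency it recovered 73% and 97%, with 7.10% of calls false. Alternatives were DESeq2 (1.42.0), limma voom, other scalings, filters and thresholds, fits with only the groups compared, blocks for the replicate number or lysate, removal of a smooth trend of gene length in each library, and leaving out each library in turn. For lists with the length trend removed, camera was run on limma voom values less the trend, and medians came from the edgeR fit. The main camera tests used the edgeR counts, so their adjusted p before and after removal come from different methods. Lengths of transcript parts were compared by permutation tests with 100000 resamples, and lists were set against 10000 random lists matched on gene length.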

Results

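The libraries measured which mRNAs were present in S2 cells, and which of them were on polysomes, when porthos was depleted. Porthos is a DEAD-box RNA helicase, and the study from which the samples come concerns a genetic program that raises mitochondrial function in invading macrophages. Input libraries held between 9648377 and 11918941 counts, and polysome libraries between 7559406 and 9453365. A count was seen for 11485 to 11864 genes in 11 libraries and for 10377 genes in replicate 3 of the polysome porthos group. That library stood apart on the second principal component (15.7% of the variance), at -41.7, where the other 11 lay between -3.07 and 12.8.

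porthos mRNA (symbol pths, FBgn0032919, chromosome 2L, 21143229 to 21145146, plus strand) was lower in all 6 libraries from porthos dsRNA cells. In input it had 222.8 ± 2.99 CPM with GFP dsRNA and 103.1 ± 6.43 CPM with porthos dsRNA (SD, n = 3), a log2 change of -1.11 ± 0.10 (SE; edgeR, adjusted p = 1.4e-07). In polysome fractions it had 320.04 ± 6.08 and 116.2 ± 24.0 CPM, a log2 change of -1.46 ± 0.10 (adjusted p = 8.0e-10). These changes in input and polysome differed by -0.35 ± 0.14 on the log2 scale, which did not pass the test (adjusted p = 0.22). The gene del overlaps porthos on the opposite strand. Its own log2 change was -0.02 in input and 0.11 in polysome, and neither passed the test.

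**Figure D1:**
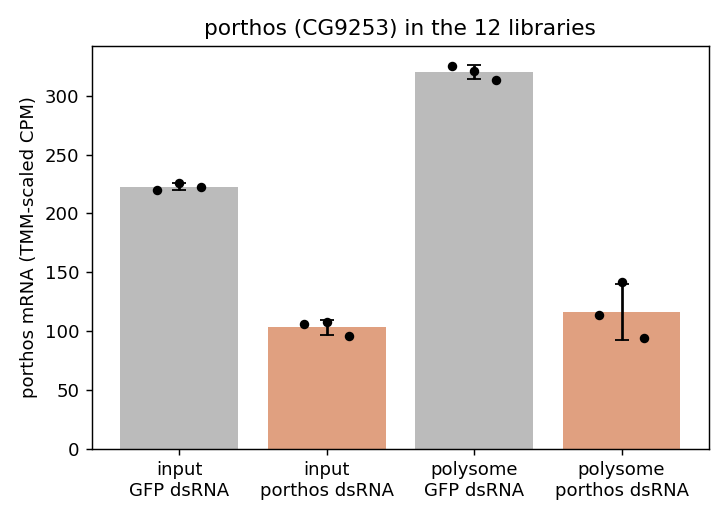
porthos mRNA in each of the 12 libraries, in CPM with TMM scaling on the vertical axis. Points are libraries, bars are group means and error bars are SD (n = 3). The 6 libraries from porthos dsRNA cells lie between 93.7 and 141 CPM, and the 6 from GFP dsRNA cells between 220.2 and 326 CPM.

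The first comparison asked which mRNAs changed in level in the lysate when porthos was depleted. Genes of plasmatocytes, the phagocytic hemocytes, were among those that rose in input. Pxn, which encodes the matrix protein peroxidasin, rose from 21.4 ± 2.41 to 48.7 ± 5.61 CPM (log2 change 1.18 ± 0.13, adjusted p = 6.0e-06). Hml, which encodes the clotting protein hemolectin, rose by 1.00 ± 0.12 on the log2 scale, and the phagocytosis receptor gene eater by 0.94 ± 0.13. CG8745 had the largest rise by the rule for named genes, from 19.8 ± 2.26 to 49.3 ± 1.42 CPM (log2 change 1.32 ± 0.10, adjusted p = 2.3e-08). CG8745 and Hml end 26 bp apart on opposite strands of chromosome 3L, so their counts may not be independent. The pyrimidine synthesis gene r (0.99 ± 0.08), CG17350 (1.06 ± 0.19), the spliceosomal RNA gene snRNA:U2:34ABa (0.84 ± 0.21) and the dosage compensation RNA lncRNA:roX1 (0.79 ± 0.09) also rose.

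After porthos itself, the largest falls in input by the rule for named genes, which leaves out genes under 10 CPM in both groups, were those of rgn (-0.77 ± 0.11, adjusted p = 0.00024), CG10486 (-0.77 ± 0.18), the integrin gene if (-0.73 ± 0.18), the zinc transporter gene Zip71B (-0.65 ± 0.17), the trehalose transporter gene Tret1-1 (-0.52 ± 0.09), CG12075 (-0.52 ± 0.13) and CG3091 (-0.50 ± 0.07). In all, 90 genes were higher and 65 lower in input with porthos dsRNA at an adjusted p under 0.05 in edgeR's quasi-likelihood test, of 9024 tested. A change of at least 2-fold was seen in 7 of the higher and 2 of the lower genes. Fitted with the input libraries alone the test called 360 higher and 331 lower genes, leaving out 1 input library left between 18 and 40 higher and between 10 and 27 lower genes, and leaving out replicate 3 of the polysome porthos group, which shares the fit, gave 138 and 121.

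Among the lists, plasmatocyte markers were higher in input. Of 10 tested members 3 rose (Pxn, Hml and eater) and 0 fell, with the same counts adjusted over the list alone, and the list passed camera with the preset and with an estimated correlation (adjusted p = 0.014 with the latter). The collagen genes Col4a1 (0.00 ± 0.10) and vkg (-0.01 ± 0.10) and the GATA factor gene srp (-0.01 ± 0.08) did not move. Germline markers lay higher without passing as a list (median 0.16, 6 of 7 above 0, adjusted p = 0.071), with bam higher (0.73 ± 0.16, adjusted p = 0.015), and their summed CPM was 392 to 401 in the input porthos and 354 to 371 in the input GFP libraries. Markers of crystal cells and lamellocytes did not pass as a list, and 2 of 6, the peroxiredoxin gene Prx2 (-0.30 ± 0.08) and the integrin gene ItgaPS4 (-0.30 ± 0.08), fell.

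All 12 glycolytic genes had a log2 change below 0 in input (median -0.20). The lactate dehydrogenase gene Ldh fell from 407 ± 11.2 to 289 ± 11.7 CPM (log2 change -0.49 ± 0.07, adjusted p = 0.00059). It was the only member called over all genes, and 6 were lower adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 1.0e-07) and not with an estimated one (adjusted p = 0.18). Tpi (-0.35 ± 0.10), Pglym78 (-0.27 ± 0.08) and Eno (-0.23 ± 0.07) did not pass the test on their own. The translation repressor gene Thor, an ATF4 target, fell by 0.41 on the log2 scale with an SE of 0.09 (adjusted p = 0.018).

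Ribosome biogenesis genes had a median of 0.16 in input, with 29 of 33 above 0. Over all genes 2 were higher, Mat89Ba (0.34 ± 0.07) and l(3)72Dn (0.42 ± 0.10), and 10 adjusted over the list alone (camera adjusted p = 9.2e-09, and adjusted p = 0.18 with an estimated correlation). Cytoplasmic ribosomal protein genes had a median of 0.14, with 68 of 79 above 0. RpL41 (0.59 ± 0.12), RpL29 (0.43 ± 0.09) and RpL18 (0.43 ± 0.11) rose, and the list's adjusted p was 0.78 with an estimated correlation. The nuclear OXPHOS list (median 0.08) and the mitochondrial ribosomal protein list (median 0.08) also lay higher, and the proteasome (median -0.09) and cell cycle (median -0.13) lists lower, with the preset correlation. With an estimated one their adjusted p was 0.78, 0.78, 0.53 and 0.53. In the cell cycle list the mitotic cyclin gene CycB fell (-0.30 ± 0.07, adjusted p = 0.026), and in the proteasome list Prosalpha6 fell (-0.28 ± 0.07, adjusted p = 0.048). The other lists did not pass in input. With fry, plasmatocyte markers (adjusted p = 0.0029), ribosome biogenesis (adjusted p = 0.016) and glycolysis (adjusted p = 0.019) passed, and no other list did.

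The second comparison asked which mRNAs changed in amount on polysomes. Here 1014 genes were higher and 644 lower with porthos dsRNA, of which 29 and 13 changed at least 2-fold. CG8745 rose from 14.1 ± 0.62 to 49.0 ± 4.03 CPM (log2 change 1.80 ± 0.11, adjusted p = 2.5e-10). CG17350 (1.39 ± 0.19), CG12133 (1.18 ± 0.11), eater (1.15 ± 0.15), Pxn (1.11 ± 0.14), CG4829 (1.07 ± 0.11) and the neprilysin-like gene Nepl20 (1.06 ± 0.08) rose as well. The co-chaperone gene stv had a log2 change of 1.33 ± 0.31, with 109 CPM in replicate 3 of the porthos group and 47.7 and 35.9 CPM in the other two. Below porthos, the largest falls by the same rule were those of CG7768 (-1.33 ± 0.24), the mucin gene Muc30E (-1.17 ± 0.21), if (-0.97 ± 0.21), the centromeric histone gene cid (-0.80 ± 0.19), CG43103 (-0.76 ± 0.23), CG11403 (-0.74 ± 0.13) and the U7 snRNP gene Lsm10 (-0.74 ± 0.19). CG7768 lies within nuf on the same strand, and its counts are uncertain for that reason. Of the genes named by the study, atos fell on polysomes (-0.41 ± 0.08, adjusted p = 0.00083) and its change in input was -0.18 ± 0.08 (adjusted p = 0.28). The difference between them did not pass (-0.23 ± 0.11, adjusted p = 0.32). CG9331 passed in none of the 3 porthos contrasts, with log2 changes of 0.11 in input and -0.11 on polysomes.

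The count on polysomes depended on single libraries. Without replicate 3 of the porthos group 599 genes were higher and 416 lower. Without replicate 1 of the GFP group the numbers were 547 and 308, and without replicate 2 of the porthos group 1252 and 1131. Of the calls 61.2% were higher, and with scaling by library size alone 45.1% were (782 higher and 953 lower genes). Without replicate 3 of the GFP group 765 genes were higher and 881 lower, and with the stricter filter 894 and 903.

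Of 33 genes of ribosome biogenesis, the assembly of ribosomal subunits in the nucleolus and cytoplasm, 22 rose and 0 fell on polysomes (24 and 1 adjusted over the list alone), with a median log2 change of 0.33. The nucleostemin gene Ns1 rose by 0.85 ± 0.08 (adjusted p = 4.7e-07), the nucleolar phosphoprotein gene Nopp140 by 0.77 ± 0.08, CG12301 by 0.70 ± 0.09 and Nnp-1 by 0.65 ± 0.08. The list's adjusted p was 1.4e-13 with the preset and 0.089 with an estimated correlation, and 0.00038 with fry. Plasmatocyte markers had 5 of 10 members higher (median 0.41, adjusted p = 0.0011, and adjusted p = 0.089 with an estimated correlation), among them Hml (0.77 ± 0.13) and Col4a1 (0.30 ± 0.10). With fry their adjusted p was 0.00060.

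Nuclear OXPHOS subunit genes went the other way on polysomes. Of 66, 15 fell and 4 rose (23 and 5 adjusted over the list alone), with a median of -0.22. The ATP synthase gene ATPsynG (-0.45 ± 0.10), the complex I genes ND-B14.5B (-0.50 ± 0.11) and ND-ACP (-0.43 ± 0.10) and the complex II gene SdhB (-0.31 ± 0.09) were among those that fell. ND-49 (0.79 ± 0.10), ATPsynbeta (0.53 ± 0.08), blw (0.35 ± 0.08) and SdhA (0.33 ± 0.08) rose. The union and the lists of complexes I and IV passed with the preset correlation (adjusted p = 0.0016, 0.015 and 0.017). Their adjusted p was 0.72, 0.72 and 0.69 with an estimated correlation, and 0.33, 0.33 and 0.22 with fry. None of them passed once a trend of gene length was removed from each library (adjusted p = 0.18, 0.23 and 0.30). Complexes II, III and V did not pass as lists.

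Other lists on polysomes mostly held members that moved both ways. The TCA cycle list lay higher (median 0.15), with 7 of 16 members higher, such as the oxoglutarate dehydrogenase gene Ogdh (0.61 ± 0.09) and the citrate synthase gene kdn (0.42 ± 0.09), and SdhB lower. The RNA interference list (median 0.14) held vig (0.57 ± 0.10) and AGO2 (0.47 ± 0.09) as called members, and the germline list (median 0.23) aub (0.63 ± 0.09) and bam (0.70 ± 0.17). Targets of ATF4 lay lower (median -0.15), with Thor (-0.62 ± 0.09), Ldh (-0.50 ± 0.07), trbl (-0.46 ± 0.09) and crc, the ATF4 gene itself (-0.26 ± 0.07), lower, and Nmdmc (0.30 ± 0.08) higher. Noncoding RNAs lay lower (median -0.16), with 22 of 387 lower and 2 higher. The adjusted p of these 5 lists was 0.034, 0.032, 0.034, 0.024 and 0.034 with fry, and 0.60, 0.48, 0.60, 0.48 and 0.48 in camera with an estimated correlation. Without replicate 3 of the polysome porthos group none of the 5 passed with the preset correlation either (adjusted p from 0.095 to 0.14), nor did OXPHOS complexes I and IV (adjusted p = 0.095 each), while the OXPHOS union, ribosome biogenesis and plasmatocyte markers did and glycolysis came to pass as lower (median -0.16, adjusted p = 0.037). Without replicate 1 of the polysome GFP group, of the 5 lists that were lower the ATF4 list still passed (adjusted p = 0.042) and noncoding RNAs (adjusted p = 0.053) and the OXPHOS union (median -0.07, adjusted p = 0.33) did not. The lists of cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis, mitochondrial import, translation factors, proteasome, p53 and cell death, heat shock proteins, immune effectors, cell cycle, crystal cells, neuron, muscle and fat body, and secretion did not pass camera. Of these lists, secretion alone passed fry (adjusted p = 0.034). Among their members, 7 of 13 secretion genes rose, led by Srp54k (0.39 ± 0.07), and 2 fell. Of 31 proteasome genes 7 rose, led by Rpt6 (0.53 ± 0.09), and 1 fell. Among immune effectors 4 of 15 fell, with the antimicrobial peptide gene CecC at -0.44 ± 0.10.

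**Figure D2:**
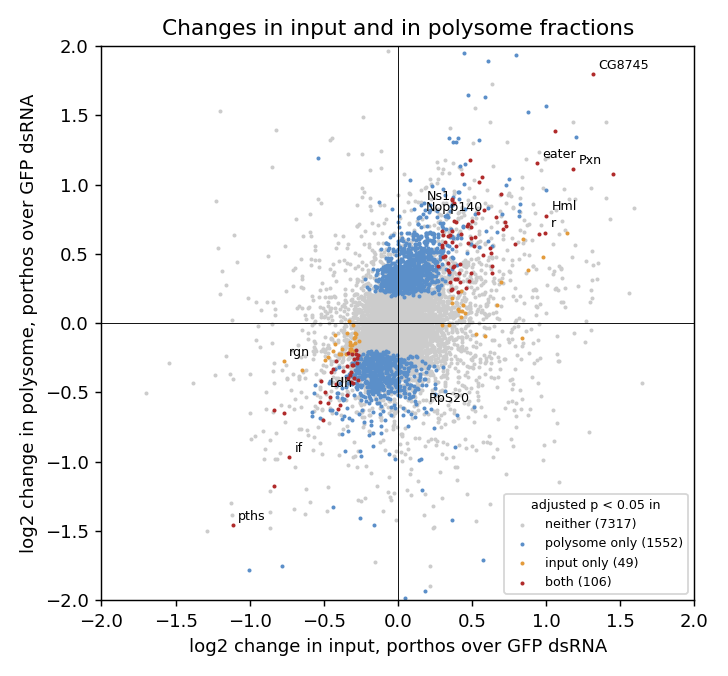
Each point is 1 of the 9024 tested genes, with its log2 change with porthos dsRNA in input on the horizontal axis and in polysome fractions on the vertical axis. Genes called in both are red (106), in polysome fractions alone blue (1552), in input alone orange (49) and in neither grey (7317), and 10 genes lie outside the axes. The called genes lie to the upper right and lower left where both passed.

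Changes in input and on polysomes went the same way where both were called. Of the 90 genes higher in input 69 were higher on polysomes, where independent lists would share 10.1, and of the 65 lower ones 37 were lower, against 4.64. None of the genes called in both (0 of 106) went opposite ways by edgeR's test. Across the 9024 genes, which are not independent replicates, Pearson's r between the changes was 0.28 and Spearman's rho 0.33. The contrasts share no library. By the protocol, however, each lysate gave an input and a polysome sample, so libraries of both contrasts can come from the same lysate. The labels do not say which ones do.

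The third comparison asked for which mRNAs the change on polysomes differed from that in input, that is, a change in translational efficiency. Such a change was called for 9 genes in the main fit, which had no term for lysates. Those higher were CG8042 (0.77 ± 0.12, adjusted p = 0.017), Ns1 (0.69 ± 0.12, adjusted p = 0.018), the aminopeptidase gene ApepP (0.66 ± 0.12), Nopp140 (0.62 ± 0.11), CG12213 (0.59 ± 0.11), the splicing factor gene Prp19 (0.58 ± 0.11) and FBgn0044510 (0.76 ± 0.15), which has no symbol in the annotation used. Ns1, for example, had 202 ± 5.13 CPM in input with GFP dsRNA and 226 ± 10.05 with porthos dsRNA, and 111 ± 9.07 and 201 ± 22.1 CPM on polysomes. Those lower were the ribosomal protein gene RpS20 (-0.78 ± 0.16, adjusted p = 0.047) and CG13751 (-1.12 ± 0.22, adjusted p = 0.047). CG8042, ApepP, Nopp140, CG12213, RpS20 and CG13751 overlap a tested gene on the opposite strand. At an adjusted p under 0.1, 114 genes were higher and 26 lower, and 1352 genes had an unadjusted p under 0.05. Other methods gave from 3 (limma voom) to 252 (DESeq2) genes at 0.05, and leaving out 1 library gave 0 genes for 7 of the 12 libraries, 79 genes without replicate 3 of the polysome GFP group and 694 without replicate 2 of the polysome porthos group. Scaling by library size alone turned the balance from 7 higher and 2 lower to 6 higher and 10 lower. With a block for the replicate number 28 genes were higher and 11 lower. With a block per lysate, which takes equal numbers of a treatment as 1 lysate, 175 were higher and 52 lower.

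Most OXPHOS subunit genes and ribosomal protein genes had a change in translational efficiency below 0 with porthos dsRNA. OXPHOS mRNAs were enriched on polysomes in GFP dsRNA cells (list median 1.02). At least 2-fold, 301 genes were higher and 251 lower on polysomes than in input with GFP dsRNA, and 62 and 193 with porthos dsRNA. A fall of lists enriched on polysomes, or a rise of depleted ones, was not told apart from this general narrowing. For nuclear OXPHOS subunits the median was -0.26 with 8 of 66 above 0, for cytoplasmic ribosomal proteins -0.20 with 3 of 79 above 0, and for mitochondrial ribosomal proteins -0.16 with 17 of 70 above 0. Over all genes 0 members were called in the first and last of these lists in edgeR's test, and RpS20 alone in the other. Adjusted over the list alone, 7 were lower and 2 higher in the OXPHOS list, 3 and 0 in the cytoplasmic and 5 and 1 in the mitochondrial ribosomal list. ATPsynG had -0.64 ± 0.14 (adjusted p = 0.052) and ND-49 0.62 ± 0.14 (adjusted p = 0.052). These lists, those of complexes I, III, IV and V, and noncoding RNAs (median -0.18) passed as lower with the preset correlation (adjusted p from 2.6e-10 to 0.028). Each had an adjusted p of 0.44 with an estimated correlation, and fry called none of the lists. With the length trend removed the mitochondrial ribosomal protein median was -0.004 (adjusted p = 0.74), and complexes III, IV and V and noncoding RNAs no longer passed (adjusted p from 0.074 to 0.23). Without replicate 1 of the polysome GFP group the OXPHOS median was -0.14 and that of cytoplasmic ribosomal proteins -0.10.

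Ribosome biogenesis (median 0.20, 23 of 33 above 0), proteasome (0.19, 26 of 31), cell cycle (0.13, 18 of 21), TCA cycle (0.15, 10 of 16) and secretion (0.25, 8 of 13) passed as higher with the preset correlation, again with an adjusted p of 0.44 with an estimated one. In the first list Ns1 and Nopp140 were called and 6 were higher adjusted over the list alone. In the others 0 were called over all genes, and 6, 6, 8 and 6 were higher adjusted over the list alone, with 1 lower in the last. Rpt6 had 0.56 ± 0.13 (adjusted p = 0.052) and Hsp60A, a mitochondrial chaperone gene, 0.37 ± 0.10 (adjusted p = 0.096). Without replicate 3 of the polysome porthos group the TCA cycle and secretion lists no longer passed (adjusted p = 0.062 and 0.080). The remaining lists did not pass.

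**Figure D3:**
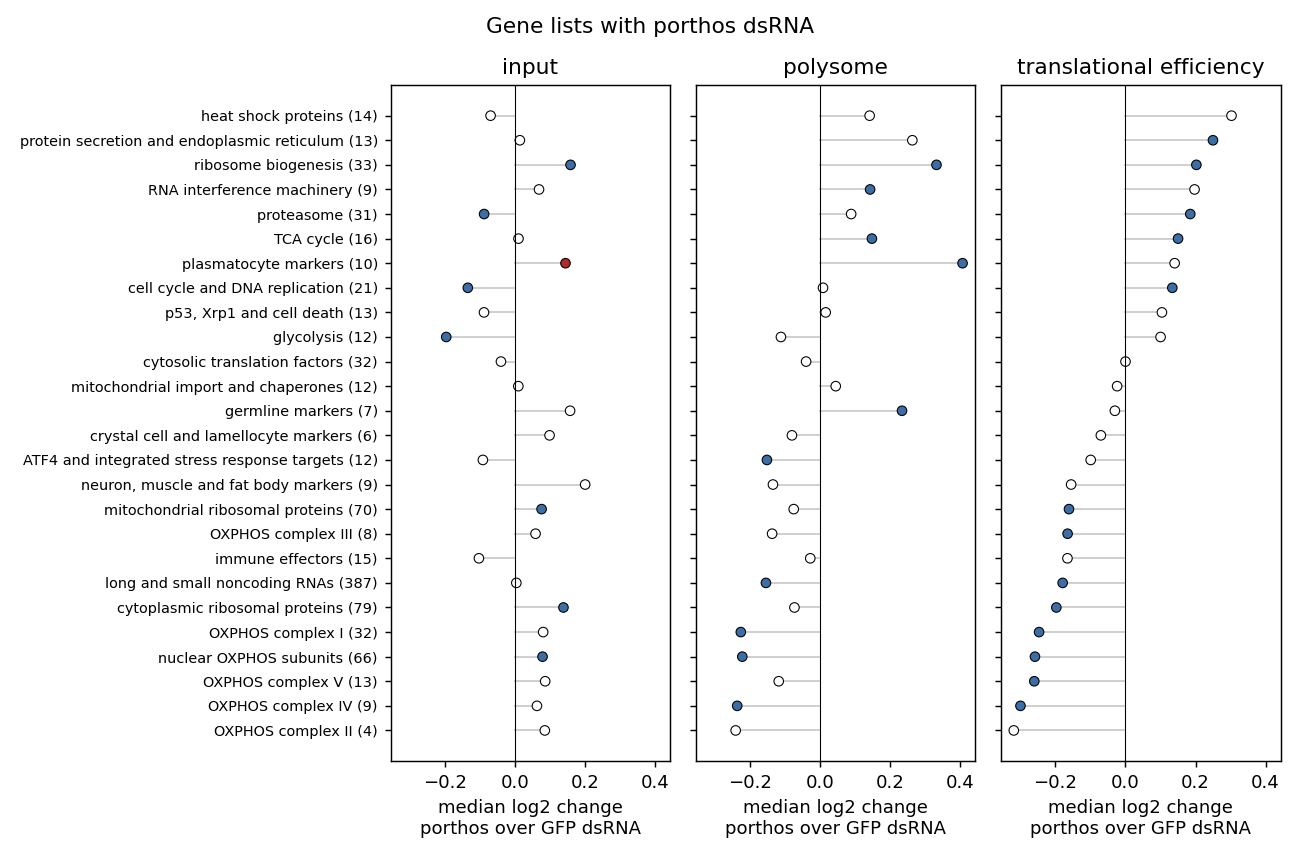
Median log2 change, porthos over GFP dsRNA, of the tested members of 26 gene lists in input, in polysome fractions and in translational efficiency. The number of tested members stands in brackets. Blue points passed camera with the preset correlation alone, the red point, plasmatocyte markers in input, also with an estimated correlation, and white points passed neither. Nuclear OXPHOS subunits lie at 0.08, -0.22 and -0.26 in the 3 panels, and ribosome biogenesis at 0.16, 0.33 and 0.20.

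The genes lower in translational efficiency had shorter coding sequences. The median was 295.5 bp for CG13751 and RpS20 and 1398 bp for 8411 genes not called, a difference of -0.69 in median log10 length (permutation test, two-sided, adjusted p = 0.031 over 6 tests), which rests on 2 genes, neither of them called once the length trend between libraries was removed (adjusted p = 0.096 and 0.079). Lengths of the 5' and 3' untranslated regions, and the lengths of the 6 higher genes with an annotated transcript, did not pass (adjusted p from 0.22 to 0.50). Against genes of like input level, the 3' untranslated regions of the higher genes were shorter (-0.57, adjusted p = 0.021), and their coding length difference turned from 0.11 to -0.04. The 3' difference did not pass with the median over annotated transcripts (-0.35, adjusted p = 0.24). Nor did it pass for the 26 higher genes of the replicate block (-0.15, adjusted p = 0.31).

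The last comparison asked which mRNAs were enriched on polysomes relative to input. RNA of the inputs and of the polysome fractions was extracted by different methods. Enrichment on polysomes and an effect of extraction therefore cannot be told apart in this comparison. In GFP dsRNA cells 2395 genes were higher on polysomes and 2605 lower, and in porthos dsRNA cells 2136 and 2175. mRNAs of OXPHOS subunits lay higher in GFP dsRNA cells, with 58 of 66 higher and 5 lower (median 1.02), for example ATPsynCF6 (1.19 ± 0.09) and ATPsynG (1.27 ± 0.10). Mitochondrial ribosomal proteins had 60 of 70 higher (median 0.74) and immune effectors 11 of 15 (median 0.84), such as CecC (1.08 ± 0.11). The RNA interference list lay lower, with 6 of 9 lower (median -0.63), including AGO1 (-1.09 ± 0.09) and AGO2 (-1.06 ± 0.09), as did cell cycle genes (14 of 21 lower, median -0.36). Cytoplasmic ribosomal proteins lay slightly higher (28 higher and 5 lower of 79, median 0.16), and this turned to a median of -0.38 when the length trend was removed. The OXPHOS median then was 0.36 and still passed, while mitochondrial ribosomal proteins (median 0.12, adjusted p = 0.096) and immune effectors (median 0.20, adjusted p = 0.12) no longer did. With an estimated correlation the adjusted p of these 6 lists was 0.19, 0.19, 0.19, 0.19, 0.36 and 0.98. With fry it was 0.00011, 4.3e-05, 4.3e-05, 4.3e-05, 0.00011 and 0.20.

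Among single genes, CG32069 (1.66 ± 0.18), CG13751 (1.62 ± 0.16), mRpL34 (1.58 ± 0.21) and Nop10 (1.49 ± 0.19) were by the rule for named genes the most enriched on polysomes after bru3, whose counts varied widely between replicates. The most depleted by that rule were the noncoding lncRNA:roX1 (-2.12 ± 0.10), lncRNA:CR32218 (-2.10 ± 0.18) and lncRNA:CR40469 (-1.69 ± 0.10) and the long mRNAs of Vps13 (-1.66 ± 0.09) and mfas (-1.62 ± 0.14). Noncoding RNAs as a list were not depleted. In GFP dsRNA cells 86 of 387 were higher on polysomes and 36 lower (median 0.22). The list did not pass camera with the preset correlation (adjusted p = 0.13) and passed fry as higher (adjusted p = 0.013). Scaling by library size alone or within each fraction moved the median gene to 0.14 and 0.12, and the share of higher calls in GFP dsRNA cells from 47.9% to 60.2% and 58.1%. In porthos dsRNA cells it moved from 49.5% to 60.9% and 63.2%.

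The difference between polysome and input followed transcript length, and here too an effect of extraction cannot be told apart from enrichment on polysomes. In GFP dsRNA cells the median log2 difference of polysome and input fell from 0.64 in the shortest of 5 length classes (73 to 1120 bp of exon) to -0.42 in the longest (3999 to 71820 bp), and in porthos dsRNA cells from 0.49 to -0.40. Across 8818 genes the Spearman correlation with length was -0.66 and -0.63. The change in translational efficiency had a median of -0.18 in the shortest class and 0.03 in the longest (Spearman 0.26), and the change in input one of 0.03 and -0.00 (Spearman -0.05).

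**Figure D4:**
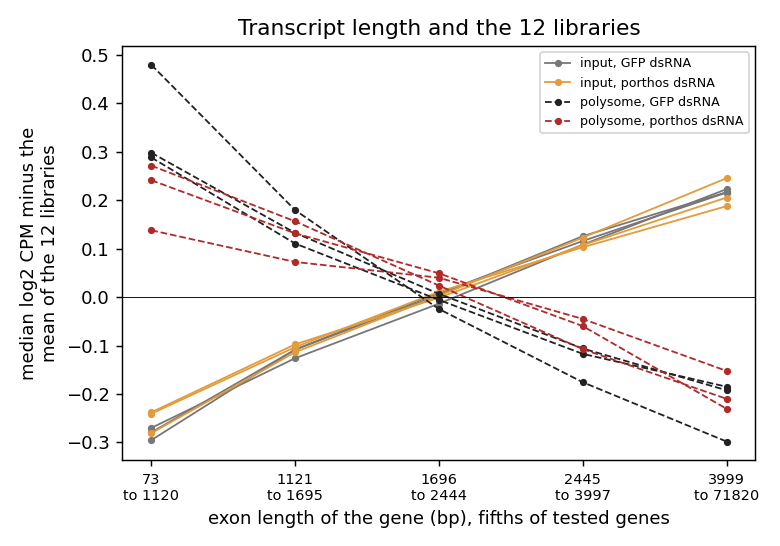
Median log2 CPM relative to the mean of the 12 libraries, for genes in 5 classes of exon length in bp, with 1 line per library. Short genes lie above 0 in each polysome library (dashed) and below 0 in each input library (solid). In the shortest class, replicate 1 of the polysome GFP group is the highest at 0.48, and replicate 3 of the polysome porthos group is the lowest polysome library at 0.14.

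The 13 mitochondrially encoded mRNAs were listed at 0 in every library and were not tested, so that nothing is said of them here. Of 111 replication-dependent histone genes, which lie in near-identical copies and whose mRNAs lack a poly(A) tail, 1 was tested, too few for a result of the list.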

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

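The depth test, the comparison of marker sums within polysome libraries and the removal of the length trend without a block were chosen only after the result was seen. With a block per lysate 175 genes were higher and 52 lower in the interaction test. In the main fit, which had no such block, the change with porthos dsRNA differed between polysome fractions and input for 9 genes. Their log2 differences were 0.77 for CG8042, 0.76 for FBgn0044510, 0.69 for Ns1, 0.66 for ApepP, 0.62 for Nopp140, 0.59 for CG12213, 0.58 for Prp19, -0.78 for RpS20 and -1.12 for CG13751. All 7 with a positive difference were higher on polysomes (edgeR, adjusted p from 2.2e-07 to 0.00010) and had an adjusted p in input between 0.067 and 0.98. Both with a negative difference were lower on polysomes (adjusted p = 0.00053 and 0.0067). With the length trend removed 6 of the higher genes remained called, FBgn0044510 has no known length and could not be corrected, and RpS20 and CG13751 moved to -0.54 (adjusted p = 0.079) and -0.80 (adjusted p = 0.096).

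Among 100 splits of the samples, 13 gave at least as many such genes as the real one's 9, so chance is not excluded by them, and the highest of the other splits gave 1554. Each of these 13 kept the polysome libraries in their real grouping or its mirror, and the 85 splits that mixed that grouping gave 0 genes at most by edgeR's test. The splits thus reflect a structure of the samples, the difference between the polysome groups, and do not separate it from a change in translational efficiency. For lists in translational efficiency the real grouping called 13. At least as many were called by 3 of the 100 splits, the real one included, a share under 0.05. The highest of the others called 15, and their median was 6. These splits regrouped input and polysome libraries independently and so separated libraries that may share a lysate. If libraries share lysates, that share does not measure chance. In input 5 of 10 splits called at least as many lists as the real one (8, with 9 the highest other), and on polysomes 4 of 10 did (10, with 12 the highest other). With 10 splits no share under 0.05 can be had. Camera with the preset correlation therefore calls lists in arbitrary groupings of these samples too.

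Nuclear OXPHOS and cytoplasmic ribosomal protein mRNAs lay lower in translational efficiency, and both lists hold short mRNAs (median exon length 879.5 and 916 bp, against 2040 bp of the genes tested). With the length trend removed, the ribosomal protein median moved from -0.197 ± 0.02 to -0.0713 ± 0.02 (SE over genes), at percentile 6.18 of 10000 lists matched on length. This lies within the bounds set for the trend. The SE and percentiles here take members of a list as independent, whereas the estimated correlation between members was 0.67 for ribosomal proteins and 0.46 for OXPHOS. The SE are therefore too small and the percentiles too extreme. The trend is not shown to account for the whole pattern, since 60 of 79 members stayed below 0 and 36.1% of the median was left. Camera with the preset correlation, run here on limma voom values less the trend, still called the list (adjusted p = 0.0078). The OXPHOS median moved from -0.26 ± 0.04 to -0.11 ± 0.03, at percentile 0.65, with 53 of 66 members below 0 and a camera adjusted p of 0.0017 with the preset correlation, whereas before removal the adjusted p of both lists was 0.44 with an estimated correlation and 0.30 and 0.31 with fry. The OXPHOS median lies below the bound of -0.1 by less than its SE, so a length effect between libraries and a further change of these mRNAs cannot be told apart. Leaving out replicate 3 of the polysome porthos group left -0.22 and -0.17, which argues against that library as the source, whereas leaving out replicate 1 of the polysome GFP group, with the steepest length trend, left -0.14 and -0.10.

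Ribosome biogenesis mRNAs lay higher in translational efficiency, by a median of 0.20 ± 0.06 (SE over genes). The length trend does not explain this, since the median was 0.20 with it removed (percentile 100 of the length-matched lists), and neither does replicate 3 of the polysome porthos group, without which it was 0.19. The SE and the percentile take members as independent, whereas the estimated correlation between them was 0.17. The list had an adjusted p of 0.44 in camera with an estimated correlation and of 0.17 with fry. In GFP dsRNA cells 18 of its 33 genes were lower and 8 higher on polysomes than in input (median -0.23). Its rise was therefore not told apart from the general narrowing of differences between polysome and input. The depletion of porthos, the difference that the design names, stays open and untested, and other technical sources were not tested.

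Replicate 3 of the polysome porthos group showed a count for fewer genes. Depth does not explain it, since at equal depth it still had 834 genes fewer than the lowest other library. A smaller number of distinct RNA molecules stays open, since genes with few counts scattered 2.65 ± 0.15 times as much as in the median of the 9 libraries outside its group (SE over resampled genes), but 1.37 ± 0.08 times as much as in the highest other library and 1.49 ± 0.10 times as much as in the highest outside its group, under the bound of 2 set beforehand. That bound was set against the highest library and so leaves a rise over most libraries unexcluded. RNA of another cell type stays open. Its germline marker sum was 1.14 times and that for neuron, muscle and fat body 1.04 times the highest of the other 5 polysome libraries. Both sums lay above the others but under the bound of 2. Against the input libraries, also of S2 cells, neither sum was high. The sums were 357 and 128 CPM in this library, and 354 to 401 and 144 to 169 CPM in the inputs.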

How the results depend on the processing

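The removal of the length trend without a block was chosen after seeing the data. The causes of the changes below were not tested, except that leaving out libraries or genes leaves fewer to test. porthos kept its fall throughout, with a log2 change from -1.16 to -1.07 in input and from -1.64 to -1.35 on polysomes when 1 library was left out.

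Without a filter 157 genes were higher and 107 lower in input, 149 and 94 in translational efficiency, and 4 lists lower in polysome than input. With the stricter filter translational efficiency gave 3 and 0 genes, as with limma voom, and the correlation of input and polysome changes was 0.41. Among genes called in either contrast it was 0.46. DESeq2 gave 125 lower genes in input, and 222 higher and 30 lower in translational efficiency, where it kept 4273 genes. Library size scaling gave 10 lower there. The rule of 2 SD, which is no test, gave 150 and 315. With only the groups compared, 360 genes were higher and 331 lower in input, and 559 and 294 on polysomes. Called changes of at least 2-fold numbered 7 and 2 in input, 29 and 13 on polysomes, and 0 and 1 in translational efficiency. In polysome against input they numbered 301 and 251 with GFP dsRNA, and 62 and 193 with porthos dsRNA.

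With the length trend removed 114 genes were lower in input, 0 lower in translational efficiency (edgeR, 1201 at an unadjusted p under 0.05), and 1339 higher and 1290 lower in polysome against input with porthos dsRNA. List calls became 3 higher and 0 lower on polysomes, 3 lower in translational efficiency, and 5 higher and 6 lower in polysome than input with GFP dsRNA, where cytoplasmic ribosomal proteins reversed to -0.38. With an estimated correlation 1 list was higher and 0 lower in input, and 0 and 0 in each of the other 3 contrasts. fry called 2 higher and 1 lower in input, 6 higher and 2 lower on polysomes, 0 and 0 in translational efficiency, and 11 higher and 6 lower in polysome than input.

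The labels do not say that replicate numbers mark a shared lysate, and the main fit did not take the numbers to pair the samples. Of 18 pairs with the same number 1 had a correlation of deviations above 0.1 (range -0.02 to 0.14), and the own number correlated best in 20 of 36 comparisons, where 12 would be expected by chance. Most of these comparisons are between libraries that cannot share a lysate. The 6 input and polysome pairs of the same number and treatment, which can, lay between 0.03 and 0.14. Within each treatment every library correlated best with its own number in the other fraction. This is a hint from the data of shared lysates, though the correlations are low. With a replicate block, translational efficiency gave 28 higher and 11 lower genes, and with a block per lysate 175 and 52. The replicate block with the length trend removed gave 144 and 144 in input, 13 higher in translational efficiency, and 1385 and 1321 in polysome against input with porthos dsRNA.

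Against a background matched on input expression, the coding length difference of the higher genes reversed from 0.107 to -0.0398 (adjusted p = 0.78, permutation test), and that of their 3' untranslated regions was -0.57 (adjusted p = 0.021). The latter passed under no other setting.

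Leaving out 1 library of the groups compared gave 18 to 40 higher and 10 to 27 lower genes in input, 547 to 1252 and 308 to 1131 on polysomes, 0 to 512 and 0 to 182 in translational efficiency, 2141 to 2451 and 2230 to 2376 in polysome against input with GFP dsRNA, and 1972 to 2176 and 1782 to 2248 with porthos dsRNA. Leaving out 1 of the other libraries, which share the fit, gave 72 to 138 and 45 to 121 in input, 776 to 953 and 576 to 673 on polysomes, 2465 to 2597 and 2427 to 2639 with GFP dsRNA, and 2085 to 2184 and 2047 to 2184 with porthos dsRNA. Lists numbered 3 to 8 higher and 2 to 4 lower in input, 2 to 6 and 1 to 8 on polysomes, 3 to 8 and 6 to 9 in translational efficiency, and 8 to 9 and 2 to 3 in polysome than input. Each group kept at least 2 libraries. Of the single genes checked, 0 reversed. These were the genes that the naming rule took for the 3 porthos contrasts, with list members only from lists that passed camera. Members of other lists, members named after their values were seen and genes named for polysome against input were not checked as such. Under the other settings 3 of 506 values in input lost their call and 37 gained one, on polysomes 10 and 13 of 581, and in translational efficiency 19 and 99 of 627. With 1 library left out 64 of 276, 15 of 318 and 78 of 684 lost it, and 0, 8 and 51 gained it. Of called lists, 83 of 287 values lost their call under the other settings and 37 of 324 with 1 library left out. Depth limits what can be said of genes near the floor of 3 counts, 0.252 to 0.397 CPM.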

Other observations

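In several lists that did not pass on polysomes, single members were called in both directions, and the members named here were chosen after their values were seen. In the proteasome list Rpt6 (0.53 ± 0.09), Rpn10 (0.41 ± 0.08), Rpt1 (0.40 ± 0.09) and Rpn5 (0.36 ± 0.09) were higher with porthos dsRNA and Prosalpha6 lower (-0.23 ± 0.07). In the mitochondrial import and chaperone list Tom70 (0.62 ± 0.09), Hsp60A (0.40 ± 0.07) and Hsc70-5 (0.31 ± 0.08) were higher, and Tim8 (-0.37 ± 0.09) and Roe1 (-0.36 ± 0.08) lower. In the cell cycle and replication list RnrS (0.52 ± 0.09), Mcm6 (0.44 ± 0.08), Mcm7 (0.39 ± 0.11) and RnrL (0.36 ± 0.08) were higher, and Cdk2 (-0.58 ± 0.14), stg (-0.32 ± 0.08) and CycE (-0.23 ± 0.07) lower. In the cell death list Ku80 was higher (0.46 ± 0.08) and rpr lower (-0.41 ± 0.07). Among immune effectors CecC (-0.44 ± 0.10), pirk (-0.37 ± 0.10) and PGRP-SA (-0.36 ± 0.10) were lower and 0 of 15 higher in edgeR's test.

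bru3 had between 1 and 3 counts in the 3 input GFP libraries, 2, 6 and 8250 in the input porthos libraries, 26, 5863 and 2053 in the polysome GFP libraries and 2690, 10092 and 1263 in the polysome porthos libraries. eIF4B had 3.88, 7.96 and 0.255 CPM in the polysome porthos libraries.

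For the number of genes called in input, 1 of 10 splits of the 6 libraries, the real one, reached 155, and the highest of the others gave 0. On polysomes it was also 1 of 10, with 1658 genes and 1 in the highest other split. For polysome against input the real split gave 5000 and 4311 genes with GFP and porthos dsRNA, and the highest others 0 each. 10 splits cannot give a share under 0.05.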
